A study of Drosophila melanogaster with 3 samples.

How the data were processed

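The data were peak lists from ChIP-seq of Combgap in whole Drosophila melanogaster embryos, collected over 0 to 24 h and of mixed sex per the labels. The line carried GFP at the C-terminal end of cg, the precipitation used an antibody against GFP, and chromatin was sonicated to 200 to 800 bp, per the labels. The labels gave 1 group of 3 biological replicates, numbered in their descriptions. No paired comparison and no contrast between groups could be made from them.

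The deposited files were 5 peak lists on dm6: 1 per replicate, 1 called on the pooled alignments and 1 thresholded by IDR from the other lists. Per the deposited text listings, each list was derived from replicate alignments and 1 control alignment shared by all replicates. The aligner, the peak caller, the IDR threshold and the identity of the control library are not given in the sources used here. The peak signal values were deposited as the authors' peak caller gave them against the control; their scale differed between lists, so signal was used as a rank or ratio within a list only. The −log10 q values were deposited by the authors for each peak, read as such by the narrowPeak convention; every peak of the thresholded list stood at the ceiling of 4.35, so they ranked nothing. The summit offsets were deposited by the authors in bp from the peak start. Read counts and read depth are unknown, so the precision that depth gives could not be stated and a peak missing from a list may reflect depth.

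All computing used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Genes and 23307 distinct transcription start sites (TSSs) of all biotypes came from the Ensembl release 115 annotation of BDGP 6.54, and sequence from the release 6 assembly with repeats marked. Peaks on 2L, 2R, 3L, 3R, 4 and X were used. The tests, their alternatives, the 26 gene lists, the 12 motifs and the rule for naming genes were fixed before the data were examined. Of the listed symbols, 11 were renamed to current ones and 2 without a protein-coding gene were left out.

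Replicates were compared by overlap of at least 1 bp, by sharing among the 1000 highest peaks and by Spearman correlation, beside 100 shuffles within chromosomes. Summits within 500 bp of a TSS and in annotation classes (5' UTR, coding exon, 3' UTR, noncoding exon, intron, intergenic, in this order of priority) were compared with 1000 random placements on the same chromosomes. A gene had a peak when a thresholded summit lay within 1 kb of any TSS. Lists of at least 5 genes were tested against the other protein-coding genes by two-sided Fisher's exact test, and beside it against 10000 random lists matched on TSS number (smallest p 2.00e-04). This matching was by classes of TSS number, and the highest class had no upper limit. Motifs were sought on either strand in 200 bp windows centred on summits and in 7913 control windows. Control windows were matched on chromosome, TSS class and GC within 2 percentage points and lay outside the pooled list, which can itself raise the ratios. Strand-collapsed 6-mers were tested in the same way. Signal near and far from start sites was compared by a permutation test with 100000 resamples. Density per Mb was given with exact Poisson 95% intervals, and summits were counted in fixed windows of 50 kb. P-values were adjusted by the Benjamini-Hochberg method within each family at 0.05, and p-values under 1e-300 are printed as 1e-300. An SD is over replicates or pairs of replicates.

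The genes named were those nearest to the 15 highest peaks, up to 4 highest members of each list past its test, the first 2 members without a peak of lists with few peaks, list genes in the 5 windows with most summits, and cg, ph-p, ph-d, ci, en, inv, Ubx, abd-A and Abd-B whatever their values. Further genes were named where the text says that a choice followed the values: the bithorax map, the noncoding genes and the genes with most summits. The analysis of GT runs by length, the X chromosome by run class, motifs in peaks without GTGTGT and in pooled peaks outside the thresholded list were also chosen after results were seen.

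Alternatives fixed in advance were other distances, windows, overlaps and numbers of top peaks, the 3956 highest thresholded peaks, the pooled list, flanking or repeat-free windows as controls, and each replicate left out. Added later were 1 summit for each of the 6030 merged regions and another draw of control windows. The methods were tested on simulated data. Of lists given peaks at 70% of members, 98.7% were called by Fisher's exact test and 97.3% against matched lists, with 0.8% and 0.5% of the other lists called over 50 simulations. Each simulated list held 26 genes, the lists did not overlap, and peaks were laid on genes at random, whatever their number of start sites. These rates therefore do not cover false calls from start-site number, linked neighbours or other list sizes. A motif added to 20% of windows was called in 10 of 10 simulations, and 0.833% of motif tests were called with none added. An added 6-mer ranked at the top in 3 of 3, with 0 called when none was added. The windows of these motif and 6-mer simulations lay at random places outside the pooled list. Their rates do not cover smaller differences in share or neighbouring summits that share sequence. A share of 56.5% near start sites was recovered as 56.45%, and 0 of 1500 overlaps differed from a direct count. Scripts did not use the text listings as measurements, and reads were not available for a new peak call. The result for 1 of the windows with most summits is not reported here.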

Results

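Combgap, a zinc-finger protein that binds GTGT elements and has been tied to the recruitment of Polycomb proteins, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole embryos of Drosophila melanogaster. The flies carried a cg transgene, the gene for Combgap, that adds green fluorescent protein (GFP) to the C-terminal end, and chromatin was recovered with an antibody against GFP. Embryos of both sexes were collected over 0 to 24 h, so each peak averages over all embryonic tissues and stages. The 3 samples were biological replicates of 1 group, and the design therefore held comparisons between replicates and between parts of the genome, with no contrast between conditions. Each replicate list and the list called on the pooled alignments held exactly 30000 peaks. Such equal counts look like a fixed cap, so weaker peaks may be left out and the lowest signals need not mark a limit of detection. The list thresholded by irreproducible discovery rate (IDR) held 7913 summits in 6331 intervals, since neighbouring summits can share an interval, and these merged into 6030 regions that covered 3.98 Mb with a median peak width of 579 bp. The read depth of the libraries is unknown, and peak signal was used only as a rank or ratio within a list. Coordinates are those of the dm6 genome build, counted from 1.

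The same loci led the peak list of every replicate. A peak in an intron of sim, the regulator of the ventral midline, ranked 1 in all 3 replicates, and the peaks upstream of 18w, a Toll-family receptor gene, ranked 2 and 3 in all 3. Of the 7913 thresholded peaks, 99.9% ± 0.0219 (SD, n = 3) overlapped a peak of a given replicate list by at least 1 bp, against a mean of 20.4% and a maximum of 21.3% in 100 shuffles within chromosomes. All but 17 overlapped a peak in every replicate list. Among the 1000 highest peaks of each list, 94.0% ± 1.33 (SD over the 3 pairs) were shared with another replicate, against a mean of 1.53% and a maximum of 3.10% after shuffling. Across thresholded peaks, which are not independent replicates, the signal ranks of replicate pairs correlated with a Spearman rho of 0.975 ± 0.00364 (SD over the 3 pairs). The thresholded list was itself selected for peaks that recur between replicates, which raises the first and last of these values. The replicate signals were also made against the same control alignment, so part of the rank correlation can come from that control, and its share is unknown.

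The 15 highest peaks lay nearest to 13 protein-coding genes, and 12 of the 15 had GTGTGT within 100 bp of the summit. The highest, at 13063583 to 13064943 on chromosome 3R, had its summit in an intron of sim, 1800 bp downstream of the nearest transcription start site (TSS). The next were intergenic on chromosome 2R, 4911 bp and 214 bp upstream of 18w (summits 20106600 and 20111297). An intron of Akt, the growth-signalling kinase, held the peak of rank 4 (3R, summit 16099888; mean replicate rank 5.00 ± 1.73, SD, n = 3). An intron of L, an eye growth gene, held that of rank 5 (2R, summit 14458177). Summits in an intron of the cg gene itself held ranks 6 and 7. Whether the cg transgene adds copies of this locus, and whether the control came from the same line, is unknown, so the ranks at cg are uncertain. Introns of yps, which encodes a Y-box RNA-binding protein, of GATAd, which encodes a GATA-type zinc-finger protein, and of homer, which encodes a postsynaptic scaffold, held ranks 8, 9 and 10. A noncoding exon 1218 bp upstream of CG15629 and an intergenic site 5254 bp upstream of CG14762 ranked 11 and 12. The 5' UTR of trx, which encodes a histone methyltransferase of the Trithorax group, held rank 13 (3R, summit 14286621). The GATA factor gene grn and the T-box gene bi followed at ranks 14 and 15, with summits 161 bp and 1939 bp upstream of a TSS. Of the 15 summits, 9 were intronic, 4 were intergenic, 1 lay in a 5' UTR and 1 in a noncoding exon. The replicate ranks of these peaks stayed within 1 to 20. Around the trx summit the reference reads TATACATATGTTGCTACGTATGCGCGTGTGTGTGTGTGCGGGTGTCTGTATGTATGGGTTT (3R, 14286591 to 14286651), and around the homer summit it reads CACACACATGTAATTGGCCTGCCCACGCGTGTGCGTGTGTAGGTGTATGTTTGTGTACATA (2L, 6722981 to 6723041).

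All 9 genes fixed in advance because of their ties to Combgap or Polycomb carried a peak at a TSS, over a wide range of ranks. The cg gene held 3 summits inside the interval 14173300 to 14176213 on 2R: 1 in the 5' UTR at rank 83, 117 bp downstream of the TSS, and 2 in an intron at ranks 6 and 7. Abd-B, the homeotic gene of the posterior abdomen, ranked 44 (mean replicate rank 48.3 ± 8.5, SD, n = 3), with 6 summits within 1 kb of its 6 start sites. The peak in the 5' UTR of ci, the transcription factor of the Hedgehog pathway, ranked 66 (63.7 ± 4.73) on chromosome 4. The neighbouring genes ph-d and ph-p, which encode Polyhomeotic subunits of a Polycomb complex, ranked 224 and 581. The ph-d and ph-p summit sequences shared 41 bases in a row, so reads could be split between these near-identical copies and their separate values are uncertain. The homeotic gene abd-A ranked 3127, the engrailed paralogue inv ranked 4222 and en ranked 6190. Ubx, the homeotic gene of the third thoracic segment, ranked 7645 (8164 ± 358 in the replicates). The en and Ubx peaks dropped out when only the 3956 highest thresholded peaks, or those among the 5000 highest of every replicate list, were counted, and inv dropped out under the first of these limits. The start-site peak of cg dropped out with 1 summit per merged region, since it shares an interval with the stronger intronic summits. GTGTGT lay within 100 bp of the summit at cg, ci and Abd-B, and at none of the other 6 start-site peaks.

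Across the bithorax complex, which holds Ubx, abd-A and Abd-B, the strongest sites lay away from the Ubx and abd-A promoters. From 16656623 to 16972236 on 3R, a span of 316 kb, the thresholded list held 47 summits, of which 25 had GTGTGT within 100 bp and 9 were among the 1000 highest. The highest, at 16869520 and rank 24, lay inside the lncRNA gene iab8 and had no GTGTGT within 100 bp. A summit inside Ubx at 16703109 ranked 372, against 7645 at its start site, and a summit inside abd-A at 16811973 ranked 368, against 3127. At Abd-B the strongest summit of the gene, rank 44, lay 213 bp upstream of a start site. This region was chosen for mapping after its values were seen.

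**Figure D1:**
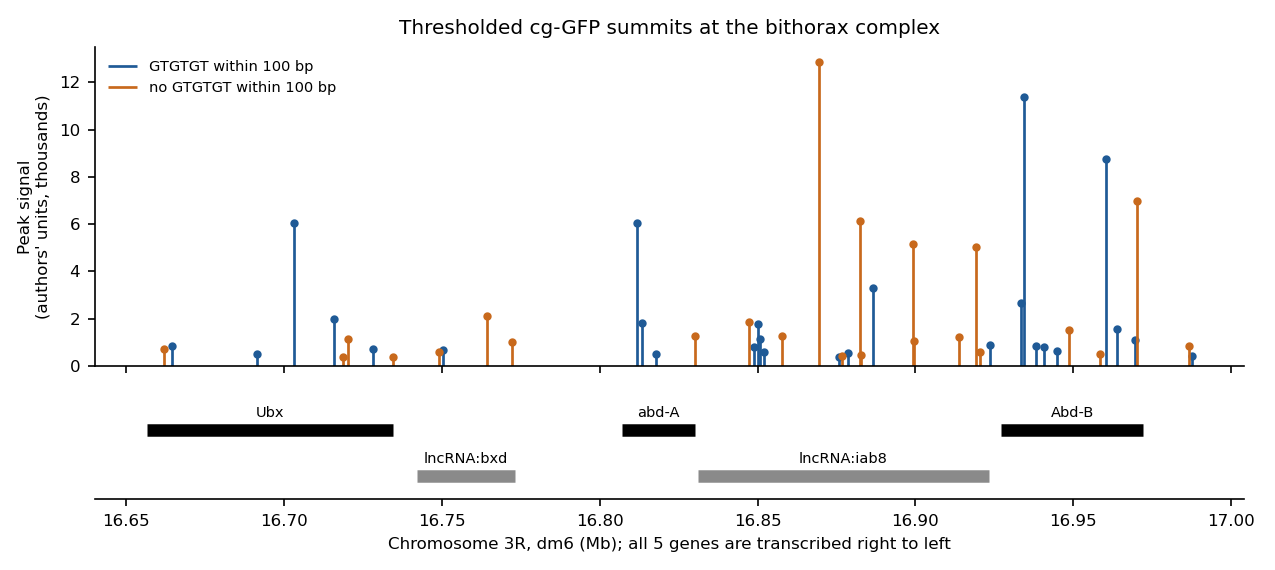
The x axis gives the position on chromosome 3R in Mb of dm6 and the y axis the peak signal in the authors' units, divided by 1000, with a stem for each thresholded summit, blue with and orange without GTGTGT within 100 bp. Bars below mark Ubx, abd-A and Abd-B (black) and the lncRNA genes bxd and iab8 (grey), and the tallest stem, rank 24, stands inside iab8 at 16869520.

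Combgap peaks were concentrated at the starts of genes and scarce in coding sequence. Summits lay within 500 bp of a TSS for 44.9% of thresholded peaks (3555 of 7913), against 13.4% of random placements on the same chromosomes, a ratio of 3.35. The 5' UTR class held 19.9% of summits against 3.4% at random (ratio 5.86), while coding exons held 1.34% against 16.7% (ratio 0.0800). Introns held 53.6% against 42.9%, noncoding exons 3.44% against 1.59%, 3' UTRs 2.31% against 4.99% and intergenic sequence 19.4% against 30.3%. Among the 1000 highest peaks of each replicate, 66.1% ± 1.33 (SD, n = 3) lay within 500 bp of a TSS. None of 1000 random placements reached the observed share near start sites (one-sided permutation p = 0.001, the smallest possible), and each annotation class lay outside its random range (two-sided permutation, adjusted p = 0.002, the smallest possible). Random placement takes no account of how well reads map or of open chromatin.

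Peaks near start sites were also stronger than the others. The median signal was 1279 for the 3555 summits within 500 bp of a TSS and 751 for the 4358 beyond, a ratio of 1.70. The thresholded summits were also compared by the signal of the peaks they overlapped in each replicate list. This covered 3553 to 3555 proximal and 4353 to 4354 distal summits per replicate. The ratio was 2.09 ± 0.0751 (SD, n = 3), with proximal summits higher in 3 of 3. These values share nearly the same selected summits, so they are not separate tests, and the full replicate lists were not compared in this way. A two-sided permutation test with 100000 resamples gave p = 1e-05, the smallest it can give, for the thresholded list. Peaks are not replicates, and neighbouring summits are not independent.

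Genes that pattern the embryo and the imaginal discs carried Combgap peaks far more often than other genes. A summit lay within 1 kb of a TSS for 22.9% of protein-coding genes (3192 of 13945), and for 8 of 8 homeotic genes and 23 of 26 imaginal disc and appendage patterning genes (88.5%). Peaks marked 20 of 30 neural fate transcription factor genes (66.7%), 15 of 22 dorsoventral patterning and mesoderm genes (68.2%), 11 of 18 Notch pathway genes (61.1%), 10 of 16 gap and terminal genes (62.5%), 7 of 10 pair-rule genes (70.0%) and 9 of 15 segment polarity genes (60%). Among the homeotic genes the highest start-site peaks after that of Abd-B belonged to Scr (rank 155), Dfd (rank 937) and pb (rank 2509). In the disc list they belonged to sd, the partner of the growth regulator Yorkie (rank 62), to the Iroquois gene mirr (rank 63), to bi (rank 70) and to the POU-domain gene nub (rank 78). The ligand genes wg and hh ranked 16 and 29, with summits 184 bp and 171 bp upstream of a TSS, and ptc, the Hedgehog receptor gene, ranked 262. SoxN, a neural Sox factor, ranked 27, and pros, which directs neural differentiation, ranked 278. The repressor gene brk, the muscle regulator Mef2 and the ligand gene dpp ranked 46, 93 and 407 in the dorsoventral and mesoderm list. In the Notch list the ubiquitin ligase gene mib1 ranked 152, the protease gene kuz 249 and E(spl)mbeta-HLH, a Notch target, 551. The head gap gene oc ranked 59, cnc 306 and hkb 415, and the pair-rule genes run and hry ranked 346 and 351.

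By Fisher's exact test (two-sided, adjusted over 26 lists), the patterning lists reached adjusted p = 5.68e-11 for imaginal discs, 3.39e-06 for neural fate, 3.34e-05 for homeotic and for dorsoventral genes, 0.00144 for Notch, 0.00185 for gap genes and 0.00404 for pair-rule and for segment polarity genes. All 8 also exceeded random lists matched on the number of start sites, with adjusted p from 8.67e-04 to 0.00851. Both tests count genes as independent, yet neighbours such as the E(spl) genes of the Notch list lie close enough to share peaks. The lists also overlap, with nub, for example, in both the disc and the neural fate list. These p-values can therefore overstate the evidence. With a distance of 5 kb the calls for gap, pair-rule and segment polarity genes ended (Fisher's exact test, adjusted p = 0.0756, 0.161 and 0.236). The segment polarity call also ended when peaks had to be among the 5000 highest of every replicate list (Fisher's exact test, adjusted p = 0.0508, and 0.0519 to 0.0560 with a replicate left out) and among the 3956 highest thresholded peaks (adjusted p = 0.127).

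Genes for chromatin regulators were marked as well. Peaks lay at 17 of 27 genes of the Trithorax group and chromatin remodelling (63.0%, adjusted p = 3.53e-05 by Fisher's exact test), among them trx at rank 13, the BET-protein gene fs(1)h at rank 60, e(y)3 at rank 345 and the Mediator gene skd at rank 580. Of the genes for factors that bind Polycomb response elements, 9 of 12 had a peak (75.0%, exact adjusted p = 5.46e-04): besides cg, the highest were z (Zeste) at rank 111, Dsp1 at rank 267 and psq at rank 579. The Polycomb group genes had peaks at 12 of 25 (48.0%, exact adjusted p = 0.0114), led by Asx at rank 154, ph-d, Su(z)2 at rank 349 and ph-p, while Sce and E(z) had none. Against lists matched on start sites the adjusted p was 8.67e-04 for the Trithorax list, 0.0442 for the response element binders and 0.0532 for the Polycomb group, and the Polycomb call also ended at 5 kb (0.0561).

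Of the lists for differentiated tissues and metabolism, 4 exceeded other genes without exceeding lists matched on start sites. Ecdysone response genes had peaks at 13 of 19 (68.4%, adjusted p = 9.87e-05 by Fisher's exact test, 0.131 against matched lists), led by the receptor gene EcR at rank 48, the nuclear receptor gene Hr39 at rank 134, Eip74EF at rank 393 and ImpL2 at rank 484. Muscle structure genes had peaks at 12 of 22 (54.5%, 0.00273, matched 0.228), led by Zasp52, a Z-disc protein gene, at rank 250 (144 bp upstream of its TSS, in an intron of tun) and Tm1, a tropomyosin gene, at rank 386. Glycolysis and citric acid cycle genes had peaks at 10 of 20 (50%, 0.0118, matched 0.684), with Pfk at rank 1141 and Eno at rank 1790, and the highest of them, at Idh3a (rank 293), lay 973 bp upstream of its TSS in an intron of CoRest. Mature neuron genes had peaks at 10 of 22 (45.5%, 0.0297, matched 0.863), led by the synaptic genes Csp at rank 813 and Syx1A at rank 2844, while nSyb and para had none. The muscle, neuron and glycolysis calls ended when peaks had to be among the 5000 highest of every replicate list (exact adjusted p = 0.123, 0.666 and 0.101) and in the 3956 highest thresholded peaks (0.505, 0.838 and 0.0579). At 5 kb the neuron and glycolysis calls ended (exact adjusted p = 0.0802 and 0.0756), and at 500 bp that of neuron genes did (0.0607).

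Chemosensory genes were nearly free of peaks. Only 4 of 119 odorant and gustatory receptor genes (3.36%, adjusted p = 5.17e-08 by Fisher's exact test) and 0 of 51 odorant binding protein genes (95% exact interval up to 6.98%, adjusted p = 1.58e-05) had a summit within 1 kb of a TSS, and both lists also fell below lists matched on start sites (adjusted p = 8.67e-04). The 4 receptor genes, Or88a, Gr97a, Gr2a and Gr5a, had their summits 634 to 885 bp upstream of a TSS, and none remained at a distance of 500 bp. The summits at Gr97a, Gr2a and Gr5a lay in UTRs of CG5521, futsch and Tre1. With a distance of 5 kb the odorant binding protein call ended (exact adjusted p = 0.0794).

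The other 9 lists did not pass the test against other genes, which does not show that they are alike. Ribosomal protein genes, active in all cells, had peaks at 19 of 85 (22.4%, 95% exact interval 14.0 to 32.7%) and mitochondrial ribosomal protein genes at 17 of 73 (23.3%), with adjusted p = 1 by Fisher's exact test for both; RpL10 and mRpL1 had none. Proteasome genes had peaks at 5 of 32 (15.6%, 0.477), cell cycle genes at 11 of 28 (39.3%, 0.0878), heat shock genes at 7 of 15 and blood cell genes at 7 of 15 (46.7% and 0.0775 each). Germ line genes had peaks at 4 of 18 (22.2%, 1), gut and fat body genes at 7 of 22 (31.8%, 0.389) and epidermis and cuticle genes at 7 of 30 (23.3%, 1). The genes without a peak included vas and osk of the germ line, CycB and CycD of the cell cycle, ple and Ddc of the cuticle, byn of the gut, lz and Hml of blood cells, and Hsp70Aa. Whether reads map well at each of them was not examined. Ribosomal protein genes passed the threshold at 5 kb (exact adjusted p = 0.0135), cell cycle genes at 500 bp (0.0184) and heat shock genes among the 3956 highest peaks (0.0461).

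**Figure D2:**
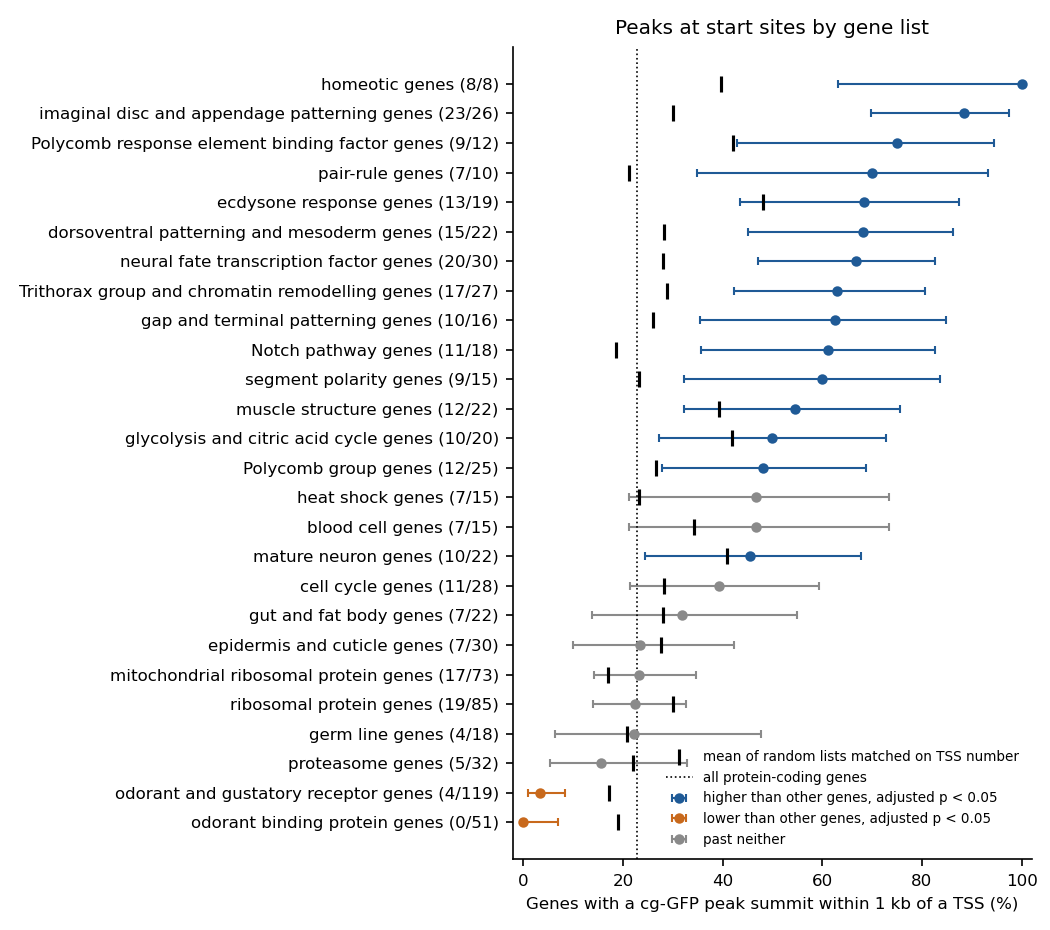
Points give the percentage of genes in each list with a thresholded summit within 1 kb of a TSS, with exact 95% binomial intervals, and black ticks give the mean of random lists matched on TSS number. The dotted line marks all protein-coding genes (22.9%), and the lists run from 8 of 8 homeotic genes to 0 of 51 odorant binding protein genes.

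GT repeats were the leading sequence at Combgap summits. GTGTGT occurred on either strand in 63.3% of the 7913 windows of 200 bp centred on summits and in 10.4% of control windows matched on chromosome, GC content and distance class to a TSS, a ratio of 6.08. In the 1000 highest peaks of each replicate it occurred in 81.7% ± 0.557 (SD, n = 3) against 10.5% ± 0.458 in controls, and was higher in 3 of 3 replicates. By position, 13.5% of summits had GTGTGT starting in the 20 bp window at the summit, and 1.38% and 1.29% did 500 bp to either side. The profile was not symmetric. Towards lower coordinates it fell to 3.88% at 140 bp and rose again to 5.13% at 220 bp, against 2.41% at 220 bp on the other side. The cause was not tested. Over 5 classes of equal size by signal, the share with GTGTGT was 79.2% in the highest and then 68.0%, 58.9%, 56.4% and 53.9%. Peaks within 500 bp of a TSS had it less often (58.5%, 95% Wilson interval 56.8 to 60.1%) than peaks beyond (67.2%, 65.8 to 68.6%).

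Of the other motifs, those of GAGA factor and Zeste were the most enriched among common ones. GAGAG, bound by GAGA factor and Pipsqueak, occurred in 41.7% of summit windows against 21.6% (ratio 1.93, exact adjusted p = 8.46e-165), and the Zeste element in 48.5% against 27.8% (ratio 1.74, adjusted p = 1.39e-158). The Dsp1 element (GAAAA) was slightly higher, 64.1% against 57.8% (5.79e-16). Rarer motifs with a higher share were Grainy head (0.556% against 0.202%, 5.77e-04), the DREF element DRE (1.05% against 0.430%, 1.25e-05) and Motif 1 of core promoters (1.02% against 0.632%, 0.0110), and the E-box CAGCTG was at 10.6% against 9.62% (0.0491). The Pho core GCCAT was lower, 29.7% against 39.2% (ratio 0.758, exact adjusted p = 1.33e-35), as were the homeodomain core TAATTA (7.23% against 9.15%, 2.02e-05) and the Sp1/KLF box (41.3% against 43.1%, 0.0256). Zelda's CAGGTA did not pass the threshold (4.59% against 5.14%, 0.112), but was lower past it with 400 bp windows (ratio 0.845, 0.00102) and with another draw of controls (0.864, 0.0437). All p-values are from two-sided Fisher's exact tests adjusted over 12 motifs, and that of GTGTGT was at the printed floor of 1e-300. The tests count the 7913 windows as independent, yet these lie in 6030 merged regions, so the p-values can overstate the evidence. GAGA, Zeste and Pho kept their direction and call in all 11 alternatives. The calls for DRE, Grainy head, Motif 1 and the homeodomain core ended in 5 to 7 of the 11. The E-box kept its call in 1 of the 11, ended in 9 and had a ratio below 1 without a call in 1. Sp1/KLF kept its call in 4, ended in 5 and had a ratio above 1 in 2, with a call only against flanking windows (1.08, exact adjusted p = 9.16e-06). Against windows 1 kb away the Dsp1 ratio was 1.00 (exact adjusted p = 0.92).

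**Figure D3:**
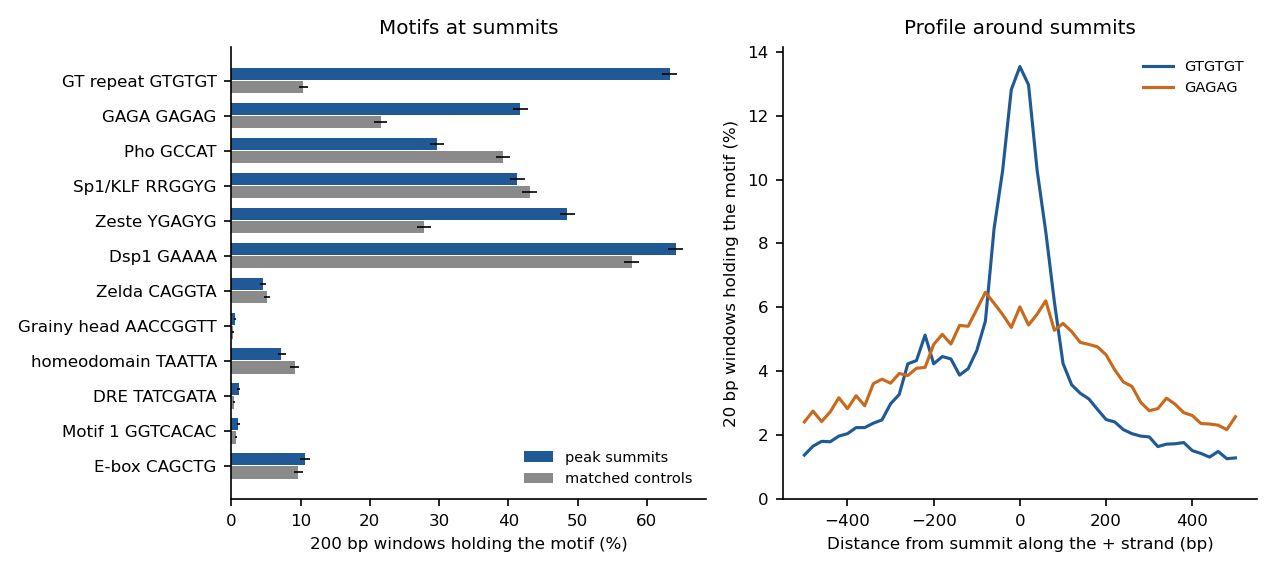
Left, bars give the percentage of 200 bp windows that hold each motif at summits (blue) and in matched control windows (grey), with 95% Wilson intervals, GTGTGT standing at 63.3% against 10.4%. Right, lines give the percentage of summits with GTGTGT (blue) or GAGAG (orange) in 20 bp windows by distance from the summit in bp, GTGTGT reaching 13.5% at the summit.

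A search over all 6-mers gave the same leading sequence. Of 2080 strand-collapsed 6-mers, 413 were more and 1145 less frequent in summit windows (Fisher's exact test, adjusted p under 0.05). A lower share, as for the Pho core, was thus common and not particular to that motif. The top was ACACAC, the reverse complement of GTGTGT, with a ratio of 6.08, then CACACA (68.0% against 12.9%, ratio 5.28), CACACG (ratio 4.55), GCACAC (4.51), ACGCAC (4.51), CGCACA (4.22), CACGCA (4.19), ACACGC (4.15), ATACAC (3.85) and TACACA (3.79). Of these 10, 8 held ACAC or CACA. Overlapping 6-mers of the same repeat are not independent, and neither are the windows of neighbouring summits.

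Longer GT runs were occupied more often, and near start sites the share levelled off from 5 units. Among GT runs in the genome, 5.52% of those of 3 units had a summit within 100 bp, 12.8% of those of 4 units and 18.8% of those of 5 units, followed by 19.7% for 6 to 8 units, 18.8% for 9 to 15 and 28.7% (95% Wilson interval 21.2 to 37.5%) for runs of 16 or more. Runs within 500 bp of a TSS were occupied more often, from 16.0% at 3 units to 46.7% at 5, 47.2% at 6 to 8 and 46.9% at 9 to 15 units. Beyond 500 bp the share rose throughout, from 3.77% at 3 units to 12.98% at 5, 16.0% at 9 to 15 and 28.04% (20.4 to 37.2%) at 16 or more. GC runs rose from 4.08% at 3 units to 9.69% at 4 and 17.5% (10.7 to 27.3%, 80 runs) at 5, and within 500 bp of a TSS from 10.2% to 17.2% and 30%, below GT runs of the same length there, with intervals that overlapped at 5 units. GA runs rose from 3.62% at 3 units to 11.4% at 6 to 8 and 16.1% (7.09 to 32.6%) at 16 or more, whereas AT runs stayed between 0.481% and 1.11%. Run lengths were compared only after the motif result had been seen, and the intervals cover counting error only.

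**Figure D4:**
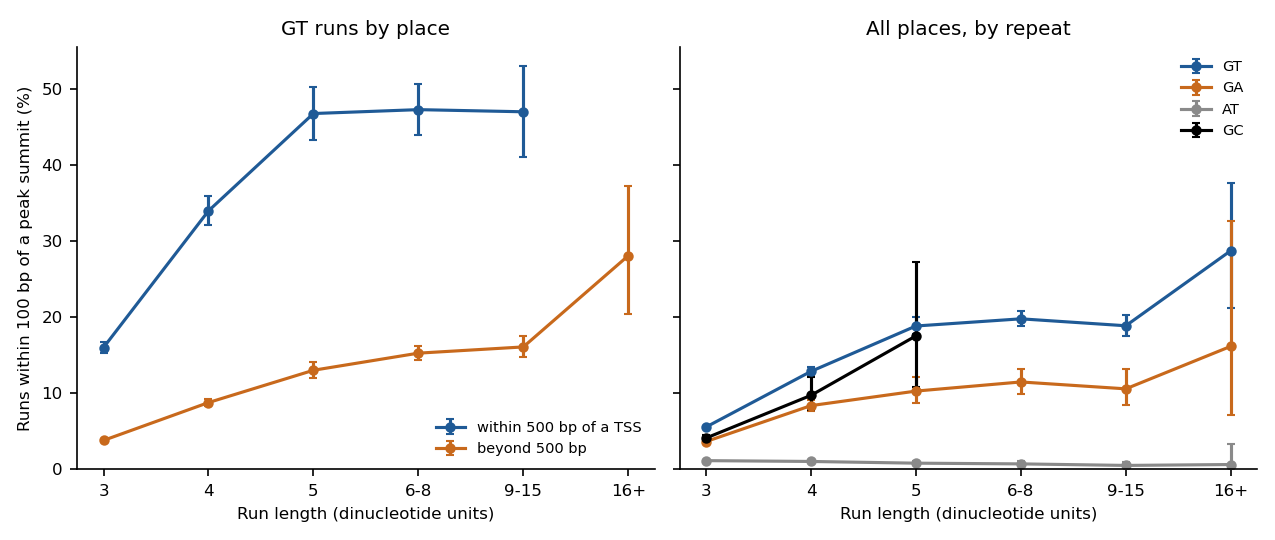
The percentage of repeat runs in the genome with a thresholded summit within 100 bp is plotted against run length in dinucleotide units, with 95% Wilson intervals. Left, GT runs within 500 bp of a TSS stand at 46.7 to 47.2% from 5 to 15 units and those beyond 500 bp rise to 28.04% at 16 or more; right, GT, GA, AT and GC runs over all places, GC reaching 17.5% at 5 units.

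The X chromosome held more Combgap peaks per Mb than any autosome arm. Peak density was 72.6 per Mb on X (95% exact Poisson interval 69.2 to 76.2), 63.1 on 2R, 57.8 on 3R, 53.5 on 3L, 51.2 on 2L and 42.1 on chromosome 4. The ratio of X to the autosome arms was 1.28 (1.22 to 1.36) for the thresholded list and 1.01 ± 0.0116 (SD, n = 3) for the 1000 highest peaks of each replicate. Among thresholded peaks it was 1.23 (1.13 to 1.32) for the 3956 highest and 1.16 (1.03 to 1.32) for the class of highest signal among 5. Windows of 200 bp with no GT run had peaks at nearly equal rates on X and autosomes (ratio 1.02, 0.922 to 1.12), windows with 5 to 8 GT units had them slightly less often on X (0.890, 0.798 to 0.992), and the ratio standardised over run classes was 0.989 (0.943 to 1.04). Outside the thresholded list, pooled peaks were denser on X by 1.70 (1.65 to 1.75). The split by GT run was chosen after the density on X had been seen, and intervals cover counting error only.

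**Figure D5:**
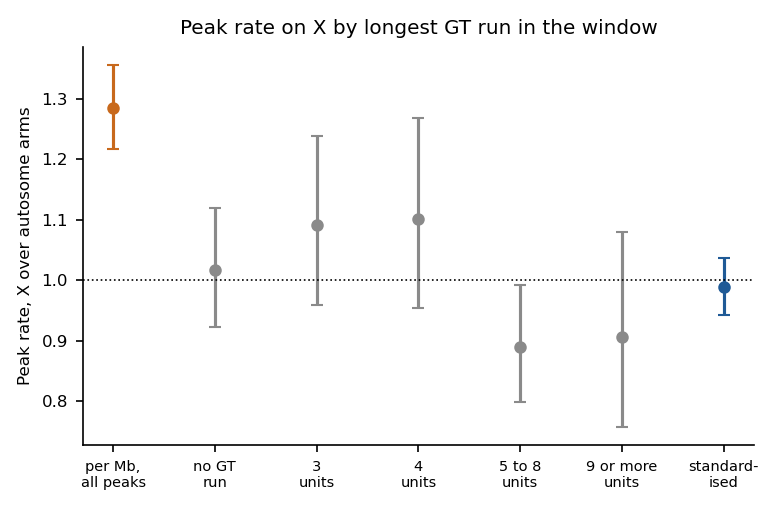
Points give the rate of thresholded peaks on X over that on autosome arms (a ratio, 1 dotted), per Mb for all peaks (orange), per 200 bp window by the longest GT run in it (grey) and standardised over these classes (blue), with 95% intervals. The ratio is 1.28 per Mb and 0.989 once run classes are standardised.

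Some windows of 50 kb held more summits than random placements gave. The 50 kb window with the most, 31 summits in 17 merged regions, lay at 11600001 to 11650000 on 2R and held tou, which encodes a chromatin remodelling protein, with Egm and atos. Next were 30 summits at 16200001 to 16250000 on 3R around tara, 24 at 10550001 to 10600000 on 2R in psq, which encodes a factor that binds GAGA sites, and 23 at 11150001 to 11200000 on 2R around shn, a zinc-finger gene of the Dpp pathway. The window at 12950001 to 13000000 on 2R with the Polycomb genes Psc and Su(z)2 held 21. The window at 10650001 to 10700000 on 3L, which holds simj, also held 21. The E(spl) complex of Notch targets on 3R, and the windows of brk and of Hr4, a nuclear receptor gene, on X held 20 each. In all, 11 windows exceeded 18 summits, the 95th percentile of the highest count in 1000 random placements with the same chromosome and TSS-proximal share, and the highest count in any placement was 26. With 1 summit per merged region the limit was 14 and 5 windows exceeded it. Among the windows named here, that of tara then led with 22, ahead of tou with 17, shn with 16 and Hr4 with 15. A further window past the limit is not among those named. The windows of psq (14), simj (13), Psc and Su(z)2 (12), the E(spl) complex (11) and brk (10) did not exceed the limit.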

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

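Peaks of the pooled list that fell outside the thresholded list were not part of any planned comparison, and their motifs were looked at only after the main results were seen. Among these 19543 peaks, 34.8% of 200 bp windows held GTGTGT, against 10.8% of matched controls (ratio 3.23). GAGAG of GAGA factor was in 27.1% against 22.6%, the Zeste element in 35.4% against 26.9% and the Dsp1 element in 60.9% against 59.3%. Grainy head sites were in 0.363% against 0.143%, the DRE in 1.11% against 0.445% and Motif 1 in 0.977% against 0.430%. The Pho core was lower, 37.2% against 38.6% (ratio 0.963), as was Zelda's CAGGTA, 4.29% against 4.79% (0.894). The higher motifs are listed because they are a signal in peaks left out by the authors' threshold, though that of Dsp1 was small (ratio 1.03). The difference from the thresholded peaks was not tested.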

How the results depend on the processing

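The share of peaks near transcription start sites stayed above random placements under every alternative (27.4 to 66.9%). The ratio for the GT repeat at peak summits stayed above 1 (3.79 to 8.39), as did the signal of TSS-proximal against distal peaks (1.58 to 2.13), and 1426 to 1555 6-mers at peak summits passed the threshold. The peak overlap between replicates was 99.4% by summit, 88.9% by reciprocal overlap of 50%, 99.99% for the 3956 highest and 99.9% for merged regions. The share of highest peaks shared between replicates was 92.4% for 500 peaks, 95.7% for 5000, 91.2% by reciprocal overlap and 92.85 to 95.45% with a replicate left out. The signal rank agreement between replicates was 0.964 for merged regions and 0.972 to 0.979 with a replicate left out. The count of gene lists with a peak at the TSS past the threshold fell from 17 to 11 at 5 kb, 12 against matched random lists, 13 among the 5000 highest of every replicate list and with each replicate left out of these, and 14 in the 3956 highest. Motifs past it fell from 11 to 7 with 100 bp windows, 6 with no masked base (773 windows), 5 in the 1000 highest peaks and 5 to 6 with a replicate left out; the last 3 use fewer windows. The Sp1/KLF ratio turned to 1.08 against flanking windows and 1.05 with no masked base, and that of the E-box to 0.991 in merged regions, the last 2 without a call. Zelda passed the threshold with 400 bp windows and another draw of controls. Of 91 named genes, 18 gained or lost a start-site peak under at least 1 alternative. At 500 bp the peaks of Syx1A and Idh3a, among others, were lost. At 5 kb Sce, CycB, lz, mRpL1, osk, para and vas, which had none at 1 kb, gained a peak. The X to autosome ratio was 1.01 in the 1000 highest peaks and 1.01 to 1.02 with a replicate left out of them. Windows with clustered summits fell from 11 to 5 at 20 kb, 5 at 100 kb, 7 in the 3956 highest and 5 with merged regions. The causes of these changes were not tested, including where fewer windows were used. In the 1000 highest peaks the ratios of DRE and Motif 1 themselves fell, from 2.44 and 1.62 to 1.23 and 1.05. With no masked base they rose, to 7.5 and 4. No paired analysis was possible because the series holds only 1 group. Read depth is unknown, so its effect on the weaker peaks could not be assessed.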

Other observations

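Noncoding genes and the place of GT runs were examined only after the main results were seen. A summit lay within 1 kb of a TSS for 561 of 3261 ncRNA genes (17.2%), 29 of 290 tRNA genes (10%), 27 of 269 snoRNA genes, 2 of 32 snRNA genes and 0 of 99 rRNA genes. How well reads map to these genes was not examined, so a low share does not show a lack of binding. In the bithorax complex the lncRNA gene iab8 had 4 such summits (highest rank 515) and bxd had 1 (rank 3722). The heat shock lncRNA gene Hsromega had 2 (rank 1938), and roX1 and roX2, which act in dosage compensation, had 0. The protein-coding genes with most summits near their start sites were Tlk, a kinase gene, with 12, and tou with 10, followed by cnc, fs(1)h, kay, par-1 and psq with 8 each. GT runs of 5 or more units had a summit within 100 bp in 49.9% of cases in 5' UTRs, 30.2% in noncoding exons, 20.1% in introns, 12.3% in intergenic sequence and 10.4% in 3' UTRs, and in 0 of 31 in coding exons (95% interval up to 11.03%). The 2906 peaks without GTGTGT were richer than their controls in GAGAG (ratio 1.96), the Zeste element (1.56), DRE (3.35), Motif 1 (2.57) and Grainy head sites (3.58), and poorer in the Pho core (0.852). These peaks can still hold the shorter GTGT, and the Motif 1 pattern GGTCACAC holds GTGT on its other strand.

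The comparison of GT repeats with other simple repeats was changed after its first outcome was seen: AT repeats alone (ratio 1.36) were replaced by AT, GA, A and GC repeats. If GT repeats at Combgap summits came from reads piled up in masked repeats, the ratio should fall to about 1 without masked bases. In the 773 windows that had none, of 7913, it was 4.1, with GTGTGT in 31.8% against 7.76% of controls. Masked repeats thus did not account for the enrichment in those windows. The check could not cover the windows with masked bases, so a part played by masked repeats there stays open. Against windows 1 kb away the ratio was 3.787, so regional base composition did not account for all of the enrichment. The highest ratio among the other repeats was 3.289, for GA, below the 6.08 of GTGTGT. Per run of 5 units, 18.8% of GT runs had a summit (95% interval 17.7 to 19.9%), against 10.2% of GA runs (8.69 to 12.1%), 0.776% of AT runs (0.556 to 1.08%) and 17.5% of GC runs (10.7 to 27.3%), and at 4 units GC runs (9.69%, 7.71 to 12.1%) lay below GT runs (12.8%, 12.3 to 13.4%), so AT, GA and shorter GC runs were occupied less than GT runs and GC runs of 5 units were too few to tell. A pull of simple repeats could contribute, and no ChIP from an untagged line was at hand to test it.

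The test of a chromosome-wide shift on X and both tests of the weaker peaks were chosen only after related results were seen, and related values were known when the standardised ratio was planned. GT runs of 5 or more units were 2.024 times as dense on X as on autosomes, and autosome rates per run class gave an X ratio of 0.9892, so GT content could account for the excess of thresholded peaks. Windows without a GT run had a ratio of 1.017, so no shift of coverage over the whole chromosome was seen among these peaks. The thresholded list starts at a signal of 372, against 65.6 in the pooled list, so it could miss a modest shift. Pooled peaks outside the thresholded list differed: the standardised ratio was 1.504 and that without a GT run was 1.616. A chromosome-wide shift of coverage between sample and control, or a biological difference of X, therefore remains possible.

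Both tests on patterning genes were chosen only after the list results were seen, and a further test, on ecdysone, muscle, neuron and glycolysis genes, was dropped. If any active promoter drew peaks, ribosomal protein genes should have them often. Of these, 22.35% did, against 69.9% of the 136 patterning genes (95% interval 61.4 to 77.4%). Proteasome (15.6%) and mitochondrial ribosomal protein genes (23.3%) were also low. Glycolysis and citric acid cycle (50%), heat shock (46.7%) and cell cycle genes (39.3%) stood above the 22.9% of all genes. None of these exceeded matched lists. The values argue only against a like pull at every active promoter, and a partial pull stays open at 1 kb. All 8 patterning lists exceeded random lists matched on start sites, so start-site number, as classed, did not account for them at 1 kb. Differences in number within a class were not covered. At 5 kb ribosomal protein genes did carry peaks more often than other genes (share ratio 1.36, exact adjusted p = 0.0135). Proteasome genes (0.977) and mitochondrial ribosomal protein genes (1.12, exact adjusted p = 0.480) did not pass there. A pull of active promoters was thus not seen in all such lists, and stays open at 5 kb. The gap, pair-rule and segment polarity calls ended (ratios 1.65, 1.68 and 1.44). Homeotic (2.41), Notch (2.14), disc (2.13), dorsoventral (1.86) and neural fate genes (1.85) kept theirs. Open chromatin at developmental genes could still contribute, and no ChIP of another factor was at hand to test it.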
